A study of Arabidopsis thaliana with 9 samples.

How the data were processed

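RNA was measured in 9 seedling libraries: 3 of water, 3 of doxycycline and 3 of EtBr. Total RNA was taken with TRIzol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. Whether poly(A) RNA was selected and whether strand was kept are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. CASAVA 1.8, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 are named, with no role or order, per the submitters' processing notes. The genome build is not given in the sources used here. Positions are those of the deposited tables. Of 29071 gene identifiers 28255 matched a RefSeq gene table of assembly TAIR10.1, and 99.98% of these had the same start and end there.

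The authors deposited 1 table for doxycycline against water (24434 genes) and 1 for EtBr against water (28956 genes). The signal values that the authors deposited per library are read counts divided by a size factor, as tested on the values: 100% in each of the 12 library columns were whole multiples of 1 step, within 0.001 of a read. For 4 columns the step lay near 1, where this test is weak. The reads so recovered for the 3 water libraries were equal in both tables for 100% of the 24319 shared genes. The deposited tables also hold the authors' group means, log2 fold changes, p-values and adjusted p-values. The authors' deposited table gives no p-value for 2 genes of doxycycline and 7 of EtBr. In it, 3430 and 15405 have an adjusted p under 0.05. The tables list 115 genes for doxycycline alone and 4637 for EtBr alone. Libraries held 17724030 to 20330871 reads. Read ratios have exact binomial intervals at 95%, and intervals and floors cover counting error only. Between replicates of a group the chi-square of reads over its degrees of freedom was at least 9.42, so no library was counted as a copy of another.

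Each treatment was tested against water with limma 3.58.1 (R 4.3.3), with a mean-variance trend, on log2(value + 1) over all genes of its table, with the 6 libraries compared, no replicate block and Benjamini-Hochberg adjustment at 0.05. Lists were tested with camera at a preset correlation of 0.01, adjusted over 23 lists, which hold 348 genes and the 2 organelle genomes. Some genes stand in several lists, such as AOX1A, ANAC013, HSP23.5, HRE2 and CYCB1;1, so results of different lists are not independent. EtBr was tested against doxycycline on the recovered reads of the shared genes, divided by median-ratio size factors of all 9 libraries. Simulations of shared controls numbered 50. The tests, lists, rule for named genes and main alternatives were fixed before the data were examined. The variance trend of limma was not among them: it was chosen after the files were seen and before any test was run. Alternatives changed the pseudocount (0.1 and 5), the filter (mean of at least 10), the threshold (0.01), the fold (2), the libraries, the replicate block, the centring, the adjustment and the set test (fry, estimated correlation). Chosen after seeing the data were the fit without a trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the authors' adjusted p, the list test between treatments, the settings of the fixed genes between treatments, group means, read ratios and list counts with 1 library left out, and some settings of the lists and the overlap. TMM in place of median-ratio size factors between treatments was also chosen after seeing the data. Of the genes, edgeR called 2853 for doxycycline, 13880 for EtBr and 13345 between them, and DESeq2 3474, 15405 and 13841.

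The rule named, among called genes with reads in both groups and a mean of at least 50 over them, the 7 with the largest rise and the 7 with the largest fall; the 2 members of each list with the smallest adjusted p; 10 genes fixed by name; and the 5 genes called in opposite directions with the smallest larger adjusted p.

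The fits were tested on simulated data drawn from the real means, library sizes and spread. Before the first such run, a bar of 60% recovery by limma was set for 4-fold changes among 200 changed genes. It was met for doxycycline against water (70% of 100 in 24434 genes) and for EtBr against doxycycline (66% in 24319), and missed for EtBr against water (22% in 28956). The bar was then dropped, and limits on bias, on false calls and on the list test were set after these values were seen. Of 2-fold changes limma recovered 20%, 11% and 2% in the same order, and edgeR recovered 89.7%, 90.3% and 76.8% of 4-fold changes among the genes it tested. With 8000 changed genes limma recovered 95.7% of 4-fold and 76.7% of 2-fold changes for doxycycline against water, and 89.9% and 57.7% for EtBr against water. Of unchanged genes 5.09 to 5.29% had a limma p under 0.05 in these simulations. Limma was kept because the unit fixed it as the main test, and a gene that did not pass is not shown to be unchanged.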

Results

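Gene expression was measured by RNA sequencing in whole 7-day-old seedlings of Arabidopsis thaliana (wild type Col-0). Seedlings received water, doxycycline, an antibiotic that blocks translation on the bacterial-type ribosomes of mitochondria and plastids, or ethidium bromide (EtBr), a dye that intercalates into DNA. Each of the 3 groups held 3 libraries. The dose and the length of treatment are not given in the labels. The listed genes held 17724030 to 20330871 reads per library. The title of the series names the mitochondrial unfolded protein response, in which nuclear genes for mitochondrial chaperones and proteases rise. Nothing states that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are deposited normalized counts, given as mean ± SD (n = 3 libraries per group), and log2 changes are on the log2(value + 1) scale, as estimate ± SE where an error is shown.

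Doxycycline raised nuclear genes known to respond to impaired mitochondria. All 20 measured members of the mitochondrial dysfunction stimulon rose, 20 also when adjusted over the list alone, with a median log2 change of 5.07 (camera adjusted p = 3.1e-28, adjusted p = 0.0395 with an estimated correlation). AOX1A (AT3G22370, chromosome 3, 7906521 to 7908746), which encodes the main alternative oxidase of the inner mitochondrial membrane, stood at 7556 ± 1778 against 487 ± 142 in water, a log2 change of 3.96 ± 0.21 (limma adjusted p = 1.8e-06). UPOX (AT2G21640, chromosome 2, 9254378 to 9255743), a mitochondrial protein gene induced by oxidative stress, stood at 3023 ± 415 against 43.2 ± 19.2. OM66, an outer membrane AAA ATPase gene, stood at 4638 ± 371 against 1285 ± 333. The transcription factor gene ANAC013 changed by 3.71 ± 0.15 and the auxin transporter gene ABCB4 by 3.94 ± 0.14 (log2).

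Among mitochondrial chaperones and proteases, 14 of 24 measured members rose, 0 fell and 10 did not pass the test. The count was 17 higher and 0 lower adjusted over the list alone, with a median log2 change of 0.64 (camera adjusted p = 8.4e-11, adjusted p = 0.11 with an estimated correlation). The members that rose were 7, 7, 7, 9 and 8 without doxycycline replicate 1, 2 and 3 and water replicate 2 and 3, in this order. HSP23.5 (AT5G51440), a small heat shock protein gene, stood at 2025 ± 467 against 206 ± 124, or 135 in water without water replicate 2. MGE1, a co-chaperone gene of mitochondrial HSP70, stood at 723 ± 65.6 against 149 ± 25.1, and the HSP70 genes MTHSC70-1 and MTHSC70-2 changed by 1.70 ± 0.12 and 1.06 ± 0.14 (log2). The chaperonin gene HSP60-2 changed by 1.31 ± 0.21. HSP60-2 did not pass without doxycycline replicate 1, 2 or 3 or water replicate 2 (limma adjusted p = 0.078, 0.087, 0.086 and 0.0591), and MTHSC70-2 did not pass without water replicate 3 (limma adjusted p = 0.0506). Among genes of the alternative respiratory chain, 7 of 12 measured members rose, 0 fell and 5 did not pass the test. The count was 8 higher and 0 lower adjusted over the list alone, with a median log2 change of 1.91, or 1.68 with members at 0 reads set to their bound (camera adjusted p = 1.2e-07, adjusted p = 0.0555 with an estimated correlation). AOX1D changed by 7.03 ± 0.47. Among the retrograde regulators, 7 of 12 measured members rose, 0 fell and 5 did not pass the test. The count was 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.1e-06, adjusted p = 0.0555 with an estimated correlation), and ANAC053 changed by 2.32 ± 0.13. The regulators that rose were 4 without doxycycline replicate 1 or 3 or water replicate 3.

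Reads of the plastid genome rose under doxycycline, from a small share of each library. Whether the transcripts themselves or their capture changed was not measured. Of the plastid genes, 80 of 107 measured members rose, 0 fell and 27 did not pass the test. The count was 89 higher and 0 lower adjusted over the list alone, with a median log2 change of 2.78, or 2.79 with members at 0 reads set to their bound (camera adjusted p = 9.6e-42, adjusted p = 0.0395 with an estimated correlation). The genes that rose were 42, 40 and 46 without doxycycline replicate 2 and 3 and water replicate 3, in this order. NDHI (ATCG01090, plastid genome, 119244 to 119762), a gene of the plastid NADH dehydrogenase-like complex, stood at 731 ± 82.4 against 2.01 ± 0.0876. MATK, a maturase gene that lies inside TRNK and can share its reads, stood at 2871 ± 179.9 against 19.6 ± 9.49. Plastid reads made up 0.12 to 0.194% of a doxycycline library and 0.0154 to 0.0176% of a water library, and ribosomal RNA 0.0265 to 0.481% and 0.0495 to 0.0904%. Of the mitochondrial genome, 6 of 76 measured members rose, 0 fell and 70 did not pass the test. The count was 5 higher and 0 lower adjusted over the list alone, with a median log2 change of 0.82, or 0.85 with members at 0 reads set to their bound (camera adjusted p = 9.8e-07, adjusted p = 0.22 with an estimated correlation). The genes that rose were 2, 0, 0, 3 and 0 without doxycycline replicate 1, 2 and 3 and water replicate 2 and 3, in this order, and those that fell were 1 without water replicate 3. Mitochondrial reads made up 0.0358, 0.00923 and 0.0848% of doxycycline libraries 1, 2 and 3, in the same order as ribosomal RNA (0.133, 0.0265 and 0.481%), against 0.0109 to 0.0194% of a water library, so replicate 2 lay below each water library. Mitochondrial ribosomal RNA can count in both shares, so their orders are not independent. RRN18, the gene of a mitochondrial ribosomal RNA, chosen here after its values were seen, stood at 2587, 285 and 6388 in these libraries and at 794, 1068 and 901 in water. COX2 and ORF25 changed by 2.66 ± 0.49 and 3.26 ± 0.64. COX2 did not pass without doxycycline replicate 1, 2 or 3 or water replicate 2 or 3 (limma adjusted p = 0.072, 0.095, 0.10, 0.0552 and 0.063), and ORF25 did not pass without doxycycline replicate 1, 2 or 3 or water replicate 3 (limma adjusted p = 0.11, 0.13, 0.12 and 0.11). ORF25 changed by 2.48 without water replicate 1. Nuclear photosynthesis genes were not called as a list (0 higher and 3 lower of 32, 0 and 3 adjusted over the list alone, camera adjusted p = 0.078), but they were called without doxycycline replicate 1 or 2 or water replicate 2 or 3 (camera adjusted p = 0.0427, 0.0381, 0.0359 and 0.0469). The photosynthesis genes lower were 1 without doxycycline replicate 2 or 3 or water replicate 1 or 2, and those higher were 1 without water replicate 1. GLK1, a regulator of chloroplast development, changed by -0.86 ± 0.11. LHCB1.1, a light-harvesting gene with near-identical copies, stood at 209 ± 38.3 against 235 ± 50.0 and did not pass the test (limma adjusted p = 0.67).

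Genes of the endoplasmic reticulum unfolded protein response fell under doxycycline. Of these, 1 of 16 measured members rose, 12 fell and 3 did not pass the test. The count was 1 higher and 12 lower adjusted over the list alone, with a median log2 change of -0.93 (camera adjusted p = 2.8e-07, adjusted p = 0.15 with an estimated correlation). The members that fell were 7 without doxycycline replicate 2, and those that rose were 0 without doxycycline replicate 1, 2 or 3 or water replicate 3. BIP2 and BIP1, near-identical genes for the luminal HSP70, stood at 1061 ± 63.7 against 3689 ± 471 and at 1600.1 ± 136 against 4213 ± 455. Among glutathione transferases, 11 of 23 measured members rose, 0 fell and 12 did not pass the test. The count was 17 higher and 1 lower adjusted over the list alone, with a median log2 change of 1.85 (camera adjusted p = 1.2e-10, adjusted p = 0.071 with an estimated correlation). GSTU24 and GSTU25, similar neighbouring genes that can share reads, stood at 3238 ± 466 against 28.9 ± 13.3 and at 3173 ± 315 against 9.94 ± 8.72, the latter 4.94 in water without water replicate 3. Among genes of abscisic acid and dehydration, 6 of 14 measured members rose, 0 fell and 8 did not pass the test. The count was 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.12 with an estimated correlation), and ABF3, a transcription factor gene of abscisic acid signalling, changed by 1.04 ± 0.13. The abscisic acid genes that rose were 1 without doxycycline replicate 1, 2 or 3 or water replicate 1 or 3. Among hypoxia genes, 6 of 15 measured members rose, 2 fell and 7 did not pass the test. The count was 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0072, adjusted p = 0.36 with an estimated correlation). PDC1, a pyruvate decarboxylase gene, stood at 1757 ± 247 against 29.3 ± 16.9. The hypoxia genes that fell were 0 without doxycycline replicate 1, 2 or 3 or water replicate 1 or 3. Of the senescence genes, 2 of 9 measured members rose, 0 fell and 7 did not pass the test. The count was 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.11 with an estimated correlation), with NAP at 0.84 ± 0.13. The senescence genes that rose were 1 without doxycycline replicate 1, 2 or 3 or water replicate 1 or 3.

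Root markers fell under doxycycline: 0 of 17 measured members rose, 7 fell and 10 did not pass the test. The count was 0 higher and 10 lower adjusted over the list alone, with a median log2 change of -1.37 (camera adjusted p = 5.4e-05, adjusted p = 0.24 with an estimated correlation). The markers that fell were 2, 1, 1, 2, 4 and 2 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order, and the median was -0.78 without doxycycline replicate 3. EXPA18, an expansin gene of root hairs, had 0 reads in the 3 doxycycline libraries and 84 in the 3 water libraries, and was at least 28.5-fold lower against a floor of 3 reads over the group. This limit was 17.42-fold without water replicate 3, whose level of 51.4 stood against 18.1 and 16.3 in the others, and 18.9-fold without doxycycline replicate 2. PRP3, a cell wall protein gene of root hairs, stood at 8.89 ± 1.05 against 129.9 ± 99.2, or 72.7 in water without water replicate 3, but it did not pass without doxycycline replicate 2 or 3 (limma adjusted p = 0.0541 and 0.0545). Among iron deficiency genes, 1 of 11 measured members rose, 3 fell and 7 did not pass the test. The count was 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0452, adjusted p = 0.36 with an estimated correlation). The iron genes that fell were 1 without doxycycline replicate 1, 2 or 3, and those that rose were 0 without doxycycline replicate 1, 2 or 3. This list was not called without doxycycline replicate 2 or 3 or water replicate 2 (camera adjusted p = 0.10, 0.074 and 0.091). IRT1, the main iron transporter gene of roots, had 1 read under doxycycline and 343 in water, a ratio of 0.0029 (95% counting interval 7.2e-05 to 0.016). Water replicate 3 carried most of these reads (levels of 45.3, 44.2 and 264 in water replicates 1, 2 and 3). Without it the ratio was 0.0074 and the log2 change -5.18, against -6.03 with it. The ratio was 0.0043 without doxycycline replicate 2, and without replicate 1, which held the 1 read, IRT1 was at least 77.6-fold lower.

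Among all genes past the test under doxycycline, the rule for named genes took these largest rises: AT3G54520, UGT74E2, GSTU25, AT5G24640, NDHI, AT1G60750 and AT5G55150, with log2 changes of 9.58 down to 7.49, the last 8.47 without water replicate 2. Without water replicate 2 UGT74E2 changed by 10.26 and AT5G24640 by 9.68, against 9.16 and 8.38 with all libraries. Without water replicate 3 AT5G24640 changed by 7.47 and GSTU25 by 9.08 (8.47 with all libraries), and without water replicate 1 UGT74E2 changed by 8.50. UGT74E2 (AT1G05680, chromosome 1, 1703002 to 1704838), a glucosyltransferase gene that acts on the auxin indole-3-butyric acid, stood at 4416 ± 1017 against 12.9 ± 17.9, or 2.58 in water without water replicate 2. AT3G54520 had 1 read in water, and its read ratio was 2946 (95% counting interval 528 to 116401), 1920.3 without water replicate 2, and at least 669 without water replicate 3, which held that read. AT1G60750 had 3 reads in water, and its ratio was 429.7 (95% counting interval 147 to 2086), or 840.3 without water replicate 2. The largest falls were those of AIR1, AT3G20380, AT4G22610, EXT6, IRT1, AT3G03670 and RHS19, with log2 changes of -6.69 to -5.84. AIR1 (AT4G12550, chromosome 4, 7439115 to 7439805) stood at 1.32 ± 0.584 against 234 ± 29.5. AT3G03670 had 2 reads under doxycycline, a ratio of 0.0056 (95% counting interval 0.00068 to 0.02), and it did not pass without doxycycline replicate 2 or water replicate 3 (limma adjusted p = 0.0505 and 0.056). Its ratio was 0.0085 without doxycycline replicate 2, and it was at least 79.5-fold lower without doxycycline replicate 3, which held both reads.

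Small changes were seen in 2 further lists under doxycycline. Chloroplast chaperones (1 higher and 0 lower of 16, 0 and 0 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.34 with an estimated correlation) were not called without doxycycline replicate 2 (camera adjusted p = 0.077). Cytosolic heat shock genes (2 higher and 0 lower of 14, 5 and 0 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.34 with an estimated correlation) were not called without doxycycline replicate 3 or water replicate 1 or 3 (camera adjusted p = 0.062, 0.0596 and 0.11). The chloroplast chaperones higher were 0 without doxycycline replicate 1, 2 or 3 or water replicate 1 or 3, and the heat shock genes higher were 1 without doxycycline replicate 2 or 3 or water replicate 1, 2 or 3. The heat shock factor gene HSFB2A changed by 0.96 ± 0.10. Lists not called were auxin (4 higher and 1 lower of 19, 4 and 1 adjusted over the list alone), jasmonate (1 higher and 1 lower of 21, 1 and 1 adjusted over the list alone), salicylate and defence (3 higher and 1 lower of 17, 3 and 1 adjusted over the list alone), ethylene (5 higher and 1 lower of 17, 7 and 2 adjusted over the list alone) and the DNA damage response (2 higher and 0 lower of 14, 3 and 0 adjusted over the list alone), with camera adjusted p of 0.53, 0.53, 0.62, 0.078 and 0.078. Auxin genes higher were 2 without doxycycline replicate 1, 2 or 3 or water replicate 3, and those lower were 2 without water replicate 2. Jasmonate genes higher were 0 without doxycycline replicate 1, 2 or 3 or water replicate 1 or 2, and those lower were 0, 0, 0, 2, 0 and 0 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order. Salicylate genes higher were 1, 0, 0 and 1 without doxycycline replicate 1, 2 and 3 and water replicate 3, in this order, and those lower were 0 without doxycycline replicate 1, 2 or 3. Ethylene genes higher were 0, 0, 0, 3, 0 and 1 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order, and those lower were 0, 0, 0, 0, 2 and 0 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order. DNA damage genes lower were 1 without water replicate 1. The auxin list had a median of -0.14 and a mean of -0.12 (log2) but ranked up with camera. The ethylene list was called without water replicate 1 (camera adjusted p = 0.027), and the DNA damage list was called without doxycycline replicate 1 or water replicate 3 (camera adjusted p = 0.0399 and 0.02). In the latter, ANAC044 changed by 4.48 ± 0.48, and ANAC085, with 1 read in water, had a read ratio of 58 (95% counting interval 10 to 2329.9), 37.8 without water replicate 2, and at least 13.2 without water replicate 3, which held that read. With limma 0 of 15 cell division genes (camera adjusted p = 0.51) and 0 of 11 anthocyanin genes (0.47) passed, 0 and 0 adjusted over the list alone, against 1 and 4 at an unadjusted p under 0.05 and 0 and 0 with edgeR. The cell division list was called without water replicate 1 (camera adjusted p = 0.0048), and anthocyanin genes higher were 1 without water replicate 3. PR1, a marker of salicylate signalling, had 5 reads under doxycycline and 6 in water, the latter all in water replicate 1, and did not pass the test (limma adjusted p = 0.90). Its read ratio was 0.819 (95% counting interval 0.198 to 3.22), 0.489 without doxycycline replicate 3, 0.534 without water replicate 2 and at least 1.09 without water replicate 1, against a floor of 3 reads over the group. In all, 2868 of 24434 genes changed (limma, adjusted p under 0.05), 1581 higher and 1287 lower. This count was 802, 809 and 777 without doxycycline replicate 1, 2 and 3, 1644 and 924 without water replicate 2 and 3, and 1425 without a variance trend in limma. The genes higher and lower were 547 and 255, 561 and 248, and 520 and 257 without doxycycline replicate 1, 2 and 3, and 938 and 706, and 662 and 262 without water replicate 2 and 3. The share higher was 55.1% with all libraries and 71.6% without water replicate 3. Water replicate 2 stood apart on the second principal component (17.0% of the variance), at -79.5 against 48.5 and 31.0 for water replicates 1 and 3.

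**Figure D1:**
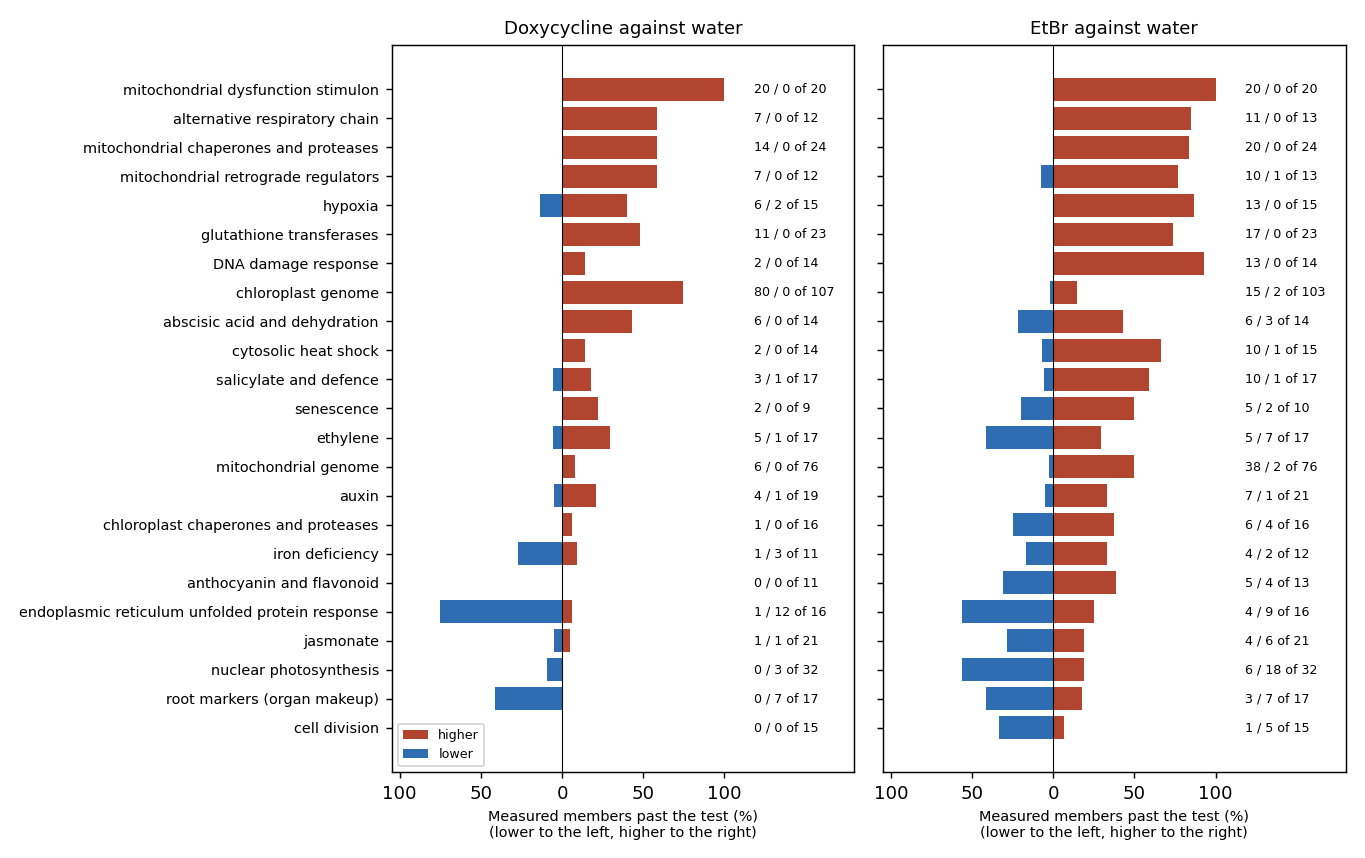
Percent of the measured members of each gene list that were higher (red, to the right) or lower (blue, to the left) than in water at a limma adjusted p under 0.05, under doxycycline (left panel) and EtBr (right panel), with the counts higher / lower of measured beside each bar. All 20 measured stimulon genes were higher in both panels.

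EtBr raised the same stimulon genes: 20 of 20 measured members rose, 0 fell and 0 did not pass the test. The count was 20 higher and 0 lower adjusted over the list alone, with a median log2 change of 5.02 (camera adjusted p = 4.7e-09, adjusted p = 0.13 with an estimated correlation). AOX1A stood at 15118 ± 2999.7 against 513 ± 154 in water, a log2 change of 4.90 ± 0.23 (limma adjusted p = 4.4e-06). UPOX stood at 12160.1 ± 2763 against 45.5 ± 20.5, OM66 at 7687 ± 909 against 1348 ± 338 and ANAC013 at 4021 ± 556 against 115 ± 13.6. Among mitochondrial chaperones and proteases, 20 of 24 measured members rose, 0 fell and 4 did not pass the test. The count was 22 higher and 0 lower adjusted over the list alone, with a median log2 change of 1.95, or 2.12 with members at 0 reads set to their bound (camera adjusted p = 3.4e-06, adjusted p = 0.34 with an estimated correlation). MTHSC70-2 (AT5G09590, chromosome 5, 2975436 to 2978750) stood at 3733 ± 306 against 533 ± 93.3, HSP60-2 at 1743 ± 121 against 334 ± 102, HSP23.5 at 5893 ± 326 against 217 ± 133 (141 in water without water replicate 2) and MGE1 at 2556 ± 363 against 156 ± 24.6. Among genes of the alternative respiratory chain, 11 of 13 measured members rose, 0 fell and 2 did not pass the test. The count was 11 higher and 0 lower adjusted over the list alone, with a median log2 change of 4.2, or 4.04 with members at 0 reads set to their bound (camera adjusted p = 1.6e-04, adjusted p = 0.13 with an estimated correlation). NDB4, an alternative NADH dehydrogenase gene, and the oxidase gene AOX1B had 0 reads in the 3 water libraries, and were at least 1421-fold and 1045-fold higher against a floor of 3 reads over the group (931-fold and 685-fold without water replicate 2). Among the retrograde regulators, 10 of 13 measured members rose, 1 fell and 2 did not pass the test. The count was 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.40 with an estimated correlation), and WRKY63 changed by 6.18 ± 0.39.

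Hypoxia and DNA damage genes rose under EtBr. Among hypoxia genes, 13 of 15 measured members rose, 0 fell and 2 did not pass the test. The count was 13 higher and 0 lower adjusted over the list alone, with a median log2 change of 3.31 (camera adjusted p = 1.6e-04, adjusted p = 0.34 with an estimated correlation). HB1 (AT2G16060), a haemoglobin gene, stood at 8024 ± 692 against 233 ± 53.1, and HRE2 (AT2G47520, chromosome 2, 19502776 to 19503702), an ethylene response factor gene of hypoxia, at 4908 ± 840.2 against 2.1 ± 1.00. HRE2 is also a member of the stimulon list. Among genes of the DNA damage response, 13 of 14 measured members rose, 0 fell and 1 did not pass the test. The count was 13 higher and 0 lower adjusted over the list alone, with a median log2 change of 2.46 (camera adjusted p = 6.2e-04, adjusted p = 0.61 with an estimated correlation). The NAC factor gene ANAC044 stood at 663 ± 124 against 3.93 ± 3.20 (2.08 in water without water replicate 3), and PARP2, a poly(ADP-ribose) polymerase gene, at 653 ± 179 against 46.9 ± 19.1. SMR5, which the rule also names, was not analysed here. Among glutathione transferases, 17 of 23 measured members rose, 0 fell and 6 did not pass the test. The count was 17 higher and 0 lower adjusted over the list alone, with a median log2 change of 2.32 (camera adjusted p = 9.6e-04, adjusted p = 0.34 with an estimated correlation), and GSTU9 stood at 10985 ± 4205 against 253 ± 73.9.

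Of the mitochondrial genome under EtBr, 38 of 76 measured members rose, 2 fell and 36 did not pass the test. The count was 38 higher and 2 lower adjusted over the list alone, with a median log2 change of 1.62, or 1.66 with members at 0 reads set to their bound (camera adjusted p = 0.012, adjusted p = 0.34 with an estimated correlation). Of the measured members, 10 had 0 reads in the 3 water libraries and over 3 under EtBr, and 17 had 1 to 3 in water. Members without a read in water are listed only through EtBr reads and can only be higher. In either direction edgeR called 27 members, against 40 with limma. RRN18, the gene of a mitochondrial ribosomal RNA, stood at 21205 ± 4064 against 968 ± 152. Copies of mitochondrial DNA in the nuclear genome can share such reads. Mitochondrial reads made up 0.359 to 0.469% of an EtBr library and 0.0109 to 0.0194% of a water library, and ribosomal RNA 0.447 to 0.719% and 0.0495 to 0.0904%. Plastid genome genes were not called as a list (15 higher and 2 lower of 103, 2 and 1 adjusted over the list alone, camera adjusted p = 0.90), with a median log2 change of 0.49, or 0.45 with members at 0 reads set to their bound. The plastid genes higher were 3 and 8 without EtBr replicate 2 and water replicate 3, in this order, and those lower were 1 without EtBr replicate 1 or 3 or water replicate 2 or 3. Among nuclear photosynthesis genes, 6 of 32 measured members rose, 18 fell and 8 did not pass the test. The count was 7 higher and 19 lower adjusted over the list alone, with a median log2 change of -0.78 (camera adjusted p = 2.8e-04, adjusted p = 0.69 with an estimated correlation). RBCS1B, a gene of the Rubisco small subunit, stood at 5601 ± 791 against 31882 ± 4511. LHCB2.1 and LHCB1.1, which have near-identical copies, rose by 1.90 ± 0.14 and 1.53 ± 0.18. Among root markers, 3 of 17 measured members rose, 7 fell and 7 did not pass the test. The count was 3 higher and 7 lower adjusted over the list alone, with a median log2 change of -0.72 (camera adjusted p = 0.0425, adjusted p = 0.69 with an estimated correlation). The markers that rose were 0, 0, 1, 0 and 0 without EtBr replicate 1, 2 and 3 and water replicate 1 and 2, in this order, and those that fell were 4 without EtBr replicate 2 or water replicate 3. This list was not called without EtBr replicate 3 or water replicate 3 (camera adjusted p = 0.068 and 0.14), nor with changes centred on the median gene (0.0564). CASP1, a gene of the root endodermis, stood at 74.1 ± 14.2 against 276 ± 50.1.

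**Figure D2:**
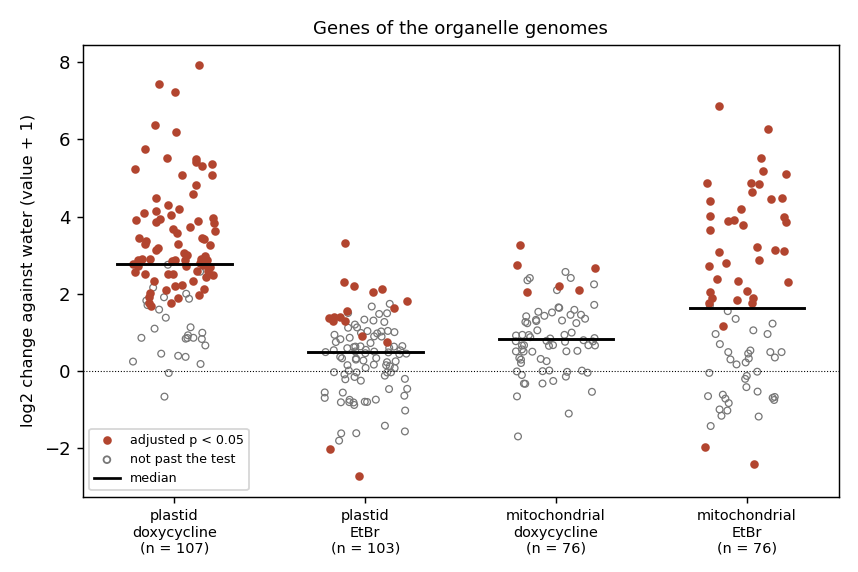
Log2 change against water, on the log2(value + 1) scale, of each listed gene of the plastid and mitochondrial genomes under doxycycline and EtBr (points, filled where the limma adjusted p was under 0.05), with a black line at the median. The plastid medians were 2.78 under doxycycline and 0.49 under EtBr, and the mitochondrial medians 0.82 and 1.62.

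The largest rises that the rule took under EtBr were those of HRE2, AT5G54450, AT4G34300, AT5G24640, SK13, AT1G70400 and AT3G58150, with log2 changes of 10.67 down to 9.90. AT5G24640 changed by 10.25, by 11.58 without water replicate 2 and by 9.33 without water replicate 3. AT5G54450, AT4G34300, SK13 and AT1G70400 had 1 read each in water. Their read ratios were 5423 (95% counting interval 973 to 214239.9), 4509.6 (95% counting interval 809 to 178155), 3926 (95% counting interval 704 to 155087) and 3712 (95% counting interval 666 to 146642). That read lay in water replicate 2 for SK13 and in water replicate 3 for the others, and without the library that held it the ratios were at least 1224, 1018, 857 and 838. Without water replicate 2 the ratios of AT5G54450, AT4G34300 and AT1G70400 were 3554, 2955 and 2432. The largest falls were those of NRT1.5, AT3G14260, AT5G26290, SLAH1, an unannotated locus, WRKY49 and AT5G44350, with log2 changes of -6.18 to -5.02. NRT1.5 (AT1G32450, chromosome 1, 11715147 to 11719988), a nitrate transporter gene, stood at 55.3 ± 16.3 against 4010.0 ± 539. Lists not called were the endoplasmic reticulum response (4 higher and 9 lower of 16, 4 and 9 adjusted over the list alone), abscisic acid and dehydration (6 higher and 3 lower of 14, 7 and 3 adjusted over the list alone), auxin (7 higher and 1 lower of 21, 6 and 1 adjusted over the list alone), ethylene (5 higher and 7 lower of 17, 5 and 8 adjusted over the list alone), anthocyanin and flavonoid (5 higher and 4 lower of 13, 5 and 4 adjusted over the list alone), iron deficiency (4 higher and 2 lower of 12, 4 and 2 adjusted over the list alone), senescence (5 higher and 2 lower of 10, 6 and 2 adjusted over the list alone), salicylate and defence (10 higher and 1 lower of 17, 10 and 1 adjusted over the list alone) and chloroplast chaperones (6 higher and 4 lower of 16, 6 and 4 adjusted over the list alone), with camera adjusted p of 0.19, 0.61, 0.66, 0.27, 0.66, 0.96, 0.37, 0.17 and 0.50. Genes of the endoplasmic reticulum response lower were 3 without EtBr replicate 1 or 2, and those higher were 2 without EtBr replicate 2. Abscisic acid genes lower were 1 without EtBr replicate 2, and auxin genes lower were 0, 2 and 0 without EtBr replicate 1 and water replicate 2 and 3, in this order. Ethylene genes lower were 4 without EtBr replicate 1 or 2, and chloroplast chaperones higher were 2 without EtBr replicate 1 or 2. Iron genes higher were 2 without EtBr replicate 2, and those lower were 0, 1, 1, 1 and 0 without EtBr replicate 1, 2 and 3 and water replicate 2 and 3, in this order. Senescence genes lower were 1 without EtBr replicate 1 or 2 or water replicate 1, 2 or 3, and salicylate genes lower were 0 without EtBr replicate 1, 2 or 3. Medians lay below 0 and means above 0 for the endoplasmic reticulum response (-0.64 and 0.13), ethylene (-0.09 and 0.32), anthocyanin (-0.35 and 0.96, the median 0.62 without water replicate 3) and chloroplast chaperones (-0.15 and 0.33). Also not called were jasmonate (4 higher and 6 lower of 21, 4 and 6 adjusted over the list alone), cytosolic heat shock (10 higher and 1 lower of 15, 10 and 1 adjusted over the list alone) and cell division (1 higher and 5 lower of 15, 1 and 5 adjusted over the list alone), with camera adjusted p of 0.11, 0.069 and 0.0539. The jasmonate list was called without EtBr replicate 3 (camera adjusted p = 0.0373), the heat shock list was called without water replicate 2 (camera adjusted p = 0.015) and the cell division list was called without EtBr replicate 2 or water replicate 1 (camera adjusted p = 0.0439 and 0.0053). Jasmonate genes higher were 2 without EtBr replicate 1 or 3, cell division genes lower were 3 without EtBr replicate 1 or 3 or water replicate 2 or 3, and heat shock genes lower were 0 without EtBr replicate 1 or 2 or water replicate 1 or 2. BZIP60, a transcription factor gene of the endoplasmic reticulum response, rose by 2.34 ± 0.12, and the chaperone gene HSP90.1 by 2.12 ± 0.22. PR1 had 36 reads under EtBr and 6 in water, the latter all in water replicate 1, and did not pass the test (limma adjusted p = 0.26). Its levels in EtBr replicates 1, 2 and 3 were 11.4, 0 and 23.2. Its read ratio was 5.30 (95% counting interval 2.21 to 15.4), 8.01 without EtBr replicate 2, 2.77 without EtBr replicate 3, 3.47 without water replicate 2 and at least 7.08 without water replicate 1, against a floor of 3 reads over the group. In all, 16040 of 28956 genes changed (limma, adjusted p under 0.05), 9906 higher and 6134 lower. Among the 24319 genes listed for both treatments, 7512 were higher and 6134 lower, so each gene called among those listed for EtBr alone was higher. The genes higher and lower were 7579 and 6091 at a mean of at least 10, 7625 and 6255 with edgeR and 8011 and 6438 with all 9 libraries in 1 fit. The median log2 change was 0.39 over all listed genes and 0.0921 over those with a mean of at least 10. EtBr replicate 3 stood apart on the second principal component (8.07% of the variance), and 15487 genes changed without it.

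**Figure D3:**
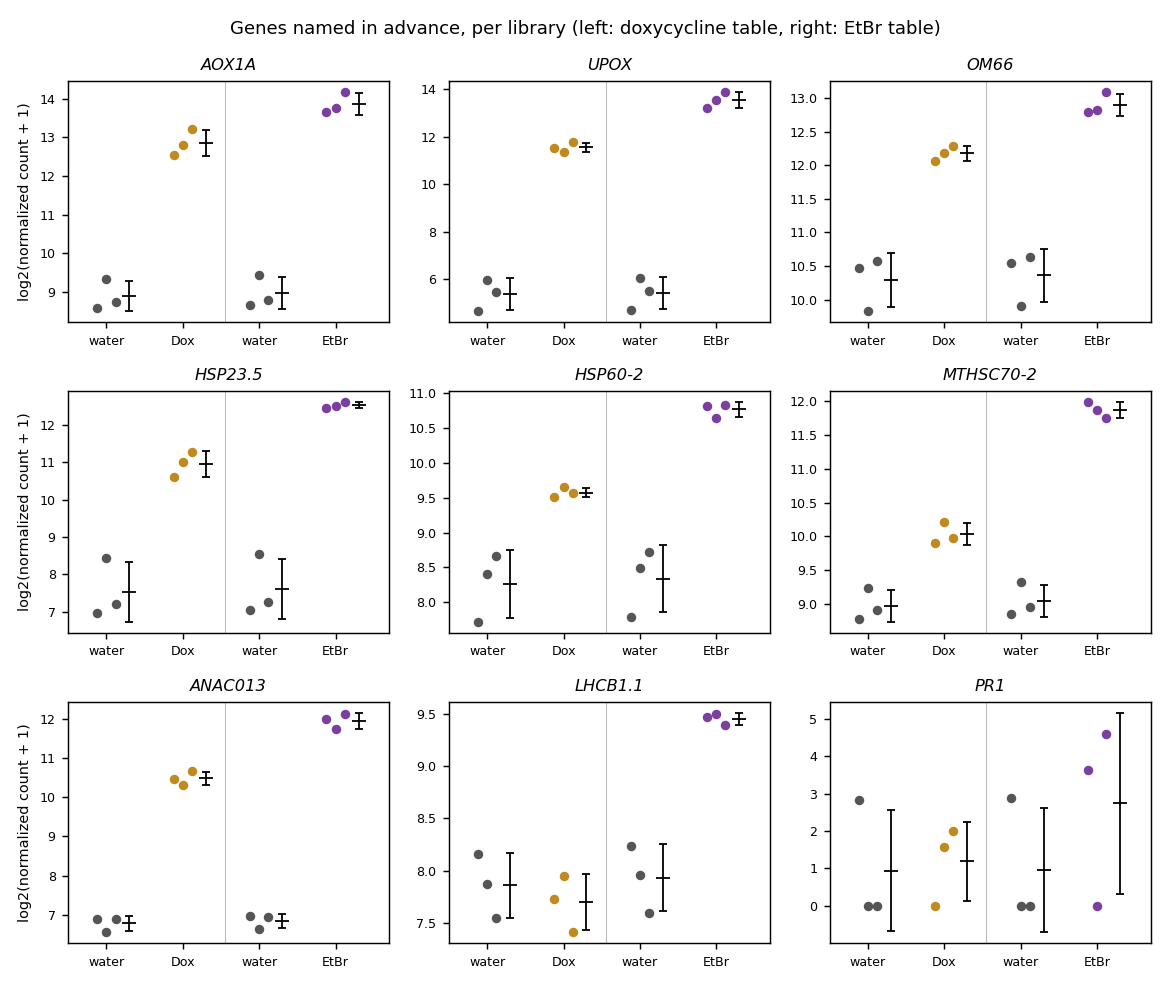
Log2(normalized count + 1) in each library of 9 genes fixed in advance, with the mean and SD of 3 libraries beside the points, for water and doxycycline (left of the grey line) and water and EtBr (right), from tables that were normalized separately. For AOX1A the means were 7556 under doxycycline and 15118 under EtBr, against 487 and 513 in water (normalized counts).

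Of the 24319 genes listed for both treatments, 1029 rose and 704 fell under both, where independent lists would share 487 and 325. Both comparisons used the same water libraries. In simulations that drew all 9 libraries from the means of the water libraries, without true changes, 1.02 genes were shared on average. With at most 21 genes called per simulated comparison, this is no benchmark for the shared count. Part of the excess may come from the shared controls. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.34 and Spearman's rho = 0.31. The simulation gave r = 0.50, but in a setting without true changes, so its r is no benchmark either. Their covariance was 0.515, where the simulation gave 0.083. Opposite directions were seen in 231 genes, 132 of them higher under doxycycline and lower under EtBr. The rule took FAR4, a fatty acyl reductase gene, CRK4, a receptor-like kinase gene, AT1G72416, AT2G23910 and ZFP6, a zinc finger gene. FAR4 changed by 1.98 ± 0.23 under doxycycline and -3.29 ± 0.44 under EtBr, and CRK4 by 1.2 ± 0.15 and -1.98 ± 0.27. Under doxycycline AT1G72416 did not pass without doxycycline replicate 2 or 3 (limma adjusted p = 0.0509 and 0.0531), and ZFP6 did not pass without doxycycline replicate 2 or 3 (limma adjusted p = 0.063 and 0.061). The 1733 genes shared in direction were 552, 566, 529, 1006 and 591 without doxycycline replicate 1, 2 and 3 and water replicate 2 and 3, in this order. The genes lower under both were 143, 147, 140, 420, 365 and 124 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order, and those higher under both 409, 419, 389, 641 and 467 without doxycycline replicate 1, 2 and 3 and water replicate 2 and 3, in this order. Opposite directions were seen in 43, 37, 45, 150, 134, 110 and 51 without doxycycline replicate 1, 2 and 3, EtBr replicate 2 and water replicate 1, 2 and 3, in this order, and genes higher under doxycycline and lower under EtBr were 19, 21, 21, 75, 55 and 25 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order, so they were not the larger part in each setting.

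EtBr was also compared with doxycycline directly, on reads recovered from both tables and put on 1 scale, because the tables were normalized separately. Mitochondrial chaperones and proteases stood higher under EtBr (21 higher and 0 lower of 24, 21 and 0 adjusted over the list alone, camera adjusted p = 7.0e-06, adjusted p = 0.095 with an estimated correlation), and plastid genome genes lower (1 higher and 67 lower of 102, 1 and 69 adjusted over the list alone, camera adjusted p = 4.1e-14, adjusted p = 0.63 with an estimated correlation). The mitochondrial genome was not called between treatments (22 higher and 3 lower of 70, 21 and 3 adjusted over the list alone, camera adjusted p = 0.24, adjusted p = 0.84 with an estimated correlation), with a median log2 difference of 0.53, and its genes lower under EtBr were 1 without doxycycline replicate 3. The log2 difference was 0.95 ± 0.21 for AOX1A, 1.13 ± 0.09 for HSP60-2, 1.76 ± 0.11 for MTHSC70-2 and 1.93 ± 0.19 for UPOX, each higher under EtBr. The plastid genes higher under EtBr were 0, 0, 0, 2, 0 and 0 without doxycycline replicate 1, 2 and 3 and EtBr replicate 1, 2 and 3, in this order, and the chaperones and proteases lower were 1 without EtBr replicate 1. In all, 13928 of 24319 genes differed (limma, adjusted p under 0.05), 7890 higher and 6038 lower under EtBr. With TMM in place of median-ratio size factors, a choice made after seeing the data, 7147 and 6759 were higher and lower. The median log2 difference of all genes was then 0.043 in place of 0.144.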

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

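The list test between treatments and the tests of RNA without poly(A) tails in general and of the plastid-encoded polymerase were chosen after the results were seen. In the direct test of EtBr against doxycycline, the effects of the treatments differed for 9 of 23 lists. Their median log2 differences, EtBr minus doxycycline, with the camera adjusted p and the adjusted p with an estimated correlation, were 1.08 for alternative respiratory chain (0.012 and 0.63), -2.50 for chloroplast genome (4.1e-14 and 0.63), 2.22 for DNA damage response (1.1e-04 and 0.84), 0.60 for endoplasmic reticulum unfolded protein response (0.03 and 0.84), 2.14 for hypoxia (4.1e-05 and 0.095), 1.24 for mitochondrial chaperones and proteases (7.0e-06 and 0.095), 1.07 for mitochondrial dysfunction stimulon (0.025 and 0.84), -0.45 for nuclear photosynthesis (0.014 and 0.84) and 0.96 for salicylate and defence (0.014 and 0.84). With the estimated correlation camera called 0 lists, against 2 at an unadjusted p under 0.05 and 15 with fry. The endoplasmic reticulum list was not called without doxycycline replicate 1 or 2 or EtBr replicate 3 (camera adjusted p = 0.0527, 0.05 and 0.15), the stimulon not called without EtBr replicate 3 (camera adjusted p = 0.065) and the photosynthesis list not called without EtBr replicate 3 (camera adjusted p = 0.065).

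Reads rose under doxycycline for 80 of 107 plastid genes (camera adjusted p = 9.6e-42, adjusted p = 0.0395 with an estimated correlation). The count was 42, 40 and 46 without doxycycline replicate 2 and 3 and water replicate 3, in this order. Under EtBr they rose for 38 of 76 mitochondrial genes (camera adjusted p = 0.012, adjusted p = 0.34 with an estimated correlation). In either direction edgeR called 27 of these genes, against 40 with limma, and 10 had 0 reads in water. Between treatments the mitochondrial genome was not called (22 higher and 3 lower of 70, camera adjusted p = 0.24, adjusted p = 0.84 with an estimated correlation). More RNA without poly(A) tails in treated libraries would raise both genomes together if capture changed alike in both organelles. Both medians lay above 0 in each treated library (mitochondrial 0.395, 1.020 and 1.251 under doxycycline, plastid 0.318, 1.098 and 0.097 under EtBr, log2), so it stays open as part of the cause. The plastid median minus the mitochondrial one was at least 1.70 in each doxycycline library and at most -0.69 in each EtBr library. This argues against a gain alike in both organelles as the whole cause. A change in tails or capture in a single organelle could give such a difference and stays open. Under doxycycline, small nuclear RNA genes (snoRNA, snRNA and tRNA) had a median change of -0.22 (bootstrap interval -0.36 to -0.02, 200 genes). This argues against a gain of these small RNA only, as far as the libraries captured them. Ribosomal RNA made up 0.133, 0.0265 and 0.481% of doxycycline libraries 1, 2 and 3, against 0.0495 to 0.0904% of a water library. It was higher than in water in libraries 1 and 3 and lower in library 2, so a gain of other RNA without tails stays open. Ribosomal RNA genes of the organelles can count in this share. Under doxycycline the median change was 3.61 for 6 genes of the nuclear-encoded polymerase and 2.59 for 9 genes of the plastid-encoded one (log2). Their difference of 1.02 (two-sided exact permutation p = 0.16) did not decide on loss of the plastid-encoded polymerase. The median of its own genes lay above 0. This argues against its loss as the whole cause for these genes, as far as reads follow transcripts. As part of the cause its loss stays open. A response of each organelle to its treatment may also underlie the pattern, as a hypothesis that was not tested.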

How the results depend on the processing

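Of 61 named genes called under doxycycline, 23 lost the call in some alternative and 20 when 1 library was left out, against 3 and 0 of 69 under EtBr, and no call turned direction in the alternatives run. The fits without a variance trend and those of the lists between treatments were chosen after seeing the data. The 2868 genes for doxycycline were 1281 at an adjusted p under 0.01, 1579 at 2-fold or more, 1425 without the trend and 777 to 1980 with 1 library left out, where fewer samples lower the power. The 1733 shared genes were 728 at 0.01, 867 at 2-fold or more and 529 to 1667 with 1 library left out. The 16040 genes for EtBr ranged over 11570 to 16013 in all alternatives, and the 13928 between treatments over 11693 to 14269. Lists called by camera were 15, 10 and 9 for doxycycline, EtBr and their difference. They were 2, 0 and 0 with an estimated correlation (8, 2 and 2 at an unadjusted p under 0.05), 13, 16 and 15 with fry, and 4 at 0.01 for the difference. With 1 library left out they were 13 to 17, 9 to 11 and 6 to 9. The anthocyanin list under EtBr, down and not called with camera, was up with fry (adjusted p = 0.0397). Camera sets a list against all other genes and fry against no change, so they ask different questions. This list had a median of -0.35 and a mean of 0.96 (log2), and all listed genes had a median of 0.39. What made the tests differ here was not tested further. The labels do not say whether replicate numbers pair the libraries. Deviations of same-numbered libraries correlated by -0.14 to 0.21, and not each correlated best with its own number. This cannot settle whether they are paired. With a replicate block 2143, 15726 and 13879 genes and 14, 11 and 9 lists were called. The count normalizations and DESeq2 in place of edgeR, planned for raw counts, were not run as planned because the values are normalized. The 3 water libraries are too few to split. Depth limits genes with few reads. In simulation limma recovered 22% of 4-fold changes for EtBr against water among 200 changed genes and 89.9% among 8000. With 16040 genes called, the latter setting lies nearer to these data.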

Other observations

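The domain test and the tests of genomic DNA and of the listing of genes were chosen after the results were seen. Genes were grouped by the family or domain name that the tables give for part of them, and tested as lists. Among genes with a pentatricopeptide repeat (PPR), a domain of organellar RNA-binding proteins, 6 of 80 rose and 0 fell (median log2 change 0.59, camera adjusted p = 3.6e-09, adjusted p = 0.94 with an estimated correlation) under doxycycline, and 52 of 80 rose and 5 fell (median log2 change 1.2, camera adjusted p = 0.0051, adjusted p = 0.86 with an estimated correlation) under EtBr. Among proteasome subunit genes 11 of 24 rose and 0 fell (median log2 change 0.35, camera adjusted p = 3.5e-05, adjusted p = 0.94 with an estimated correlation) under doxycycline, and 21 of 24 rose and 0 fell (median log2 change 0.86, camera adjusted p = 0.012, adjusted p = 0.89 with an estimated correlation) under EtBr. Among NAC factor genes 24 of 94 rose and 2 fell (median log2 change 0.51, camera adjusted p = 8.3e-05, adjusted p = 0.94 with an estimated correlation) under doxycycline. Among histone genes 28 of 37 rose and 2 fell (median log2 change 2.26, camera adjusted p = 0.0014, adjusted p = 0.89 with an estimated correlation) under EtBr, and among MADS-box genes 54 of 90 rose and 7 fell (median log2 change 2.48, camera adjusted p = 1.3e-04, adjusted p = 0.59 with an estimated correlation). Among NB-ARC genes, many of them immune receptors, 9 of 79 rose and 40 fell (median log2 change -0.71, camera adjusted p = 1.3e-04, adjusted p = 0.65 with an estimated correlation) under EtBr. In all, camera called 10 of 205 domains for doxycycline and 24 of 220 for EtBr, and with an estimated correlation 0 and 0 (6 and 14 at an unadjusted p under 0.05). Of all 28956 genes listed for EtBr, 9906 were higher and 6134 lower. Genes without a read in water are listed there only through EtBr reads and can only be higher. For families that hold such genes, part of the rise under EtBr is fixed by the listing. The PPR and proteasome groups held 80 and 24 genes for both treatments.

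More genes had reads in the EtBr libraries than in the water libraries. With each EtBr library thinned to the 17724164 reads of the shallowest water library, at most 2514 listed genes had 0 reads, against 5916 to 6500 in water. This gap cannot decide on depth, because 4285 listed genes have no read in water and are listed through EtBr reads alone. Genomic DNA would favour plastid genes, which have many copies, although EtBr may itself deplete plastid DNA. Their median gain per kb was 1.56 times that of nuclear genes without a read in water (bootstrap interval 0.757 to 2.29), below the 10 times set as the bound. Those nuclear genes are listed only through their EtBr reads, which raises their gain and lowers the ratio. The test therefore cannot decide, and genomic DNA stays open. Mitochondrial reads, which it did not use, made up 0.359 to 0.469% of an EtBr library and 0.0109 to 0.0194% of a water library. Of the 24434 genes listed for doxycycline, in a table without EtBr libraries, at most 1141 had 0 reads in an EtBr library (with 115 that lack an EtBr row counted as 0), against 1528 to 2052 in water, which argues against the listing as the cause for these genes. The libraries were not thinned for this count. EtBr replicate 3 held 19587059 reads, and water replicate 1 held 19903819 with 1797 of these genes at 0, so a deeper water library still had more genes at 0. For the 4637 genes listed for EtBr alone the listing stays open, since it fixes that the 4285 of them without a read in water have reads under EtBr, and a broad response of silent genes to EtBr stays open, as a hypothesis that was not tested.

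Root markers fell under doxycycline (7 of 17 genes, camera adjusted p = 5.4e-05, adjusted p = 0.24 with an estimated correlation, with 2, 1, 1, 2, 4 and 2 without doxycycline replicate 1, 2 and 3 and water replicate 1, 2 and 3, in this order). A smaller share of root tissue would lower them all by 1 factor only if each marker were confined to roots and spread alike within them. Cochran's Q over its degrees of freedom was 11.7, above the bound of 2, which points to unequal falls. Where the markers are expressed was not measured, so this test cannot decide and a smaller share of root tissue stays open. A response of root hair genes also stays open, as a hypothesis that was not tested.

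The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. The real split gave 2868 genes for doxycycline, 16040 for EtBr and 13928 for their difference, and 1 of the 10 splits gave as many in each. The highest of the other splits gave 0 genes in each with limma, with 952, 513 and 618 at an unadjusted p under 0.05, and 0 with edgeR. Each of these splits mixes both groups compared, so the treatment effect adds to the spread and lowers the calls. Their 0 is therefore no benchmark for an absent effect.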
